A study of Mus musculus with 6 samples.

How the data were processed

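Single-nucleus RNA sequencing was done on epididymal white adipose tissue of wild-type mice fed a low-fat diet (LFD) or a high-fat diet (HFD). There were 6 libraries, 3 per diet, numbered by experiment in the labels. Per the labels' protocols, the tissue was perfused, minced and homogenised, and nuclei were filtered, centrifuged and loaded on the 10x system with the 3' v2 kit (experiments 1 and 2, 18 weeks of diet) or the v3 kit (experiment 3, 22 weeks). The files deposited by the authors hold whole-number UMI counts per gene and barcode for every barcode with at least 1 count, not only nuclei, and a list of barcodes that the authors took as nuclei. Cell Ranger and the mm10 build are named in the submitters' processing notes; the version, the annotation, the treatment of intronic reads and the filter behind the list of nuclei are not given in the sources used here. Counts were not normalised by the authors, since library totals differ and values are whole.

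The 6 libraries held 30876 genes in all. Gene IDs were matched to symbols and positions with an mm10 annotation; 386 genes had no symbol and 8 shared one. All 28208 listed nuclei had at least 1000 UMIs, and the lowest nucleus in the v3 libraries had 1692 (LFD) and 1523 (HFD). Scrublet (in scanpy 1.11.5, expected rate 0.06, seed 0) called 112 doublets, 0.397% of nuclei, which is too few for the caller to be taken as having worked. Its calls were removed all the same, as planned, and removing the highest 6% of doublet scores of each library was added as an alternative. The kept nuclei numbered 5410, 4796 and 3944 at LFD and 5027, 4430 and 4489 at HFD. Over all 15 pairs of libraries, chi-square values per gene lay between 48.5 and 250, so no library was a repeat of another.

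UMIs were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were scaled within each library, and nuclei were clustered jointly by the Leiden method (resolution 1.0, igraph 0.11.9) on 15 neighbours in 30 principal components. A cluster was named after a cell type only from marker lists, with at least 3 detected markers and no contradiction among its top 10 genes by fold. Names are therefore given as "macrophage-like" and so on. Adipocyte-like, fibroblast or progenitor-like and macrophage-like nuclei were clustered again (resolution 0.5), leaving out genes called between diets in the class. Scaling within each library dampens differences in composition between libraries.

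The number of nuclei per class and library was tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with the log of kept nuclei as offset and the kit as a covariate, beside an exact two-sided permutation test whose smallest p with 3 against 3 libraries is 0.1. For genes, UMIs were summed per class and library, and the sums were tested with edgeR's quasi-likelihood test (robust, TMM, filterByExpr, kit as covariate, Benjamini-Hochberg adjusted p under 0.05). A class was tested only if each library held at least 20 of its nuclei, which left out the endothelial-like, immune cell-like other than macrophage-like and epididymal epithelial-like classes. Levels of genes in a class are CPM (a gene's UMIs scaled to the library's TMM-adjusted sum of tested genes for the class). Levels of marker lists and of near-empty barcodes are scaled to the plain sum. Log2 changes are those of the edgeR fit, and the log2 ratios of single experiments use a prior count of 2. The difference between the diet effects at 22 and 18 weeks was tested as the interaction of diet and kit, in edgeR and, as an added alternative, in DESeq2 1.42.0.

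Sets of genes were tested over 31 lists with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry, with adjustment over lists and classes. Lists overlap, so their results are not independent. The lipid-associated macrophage list shares Lipa, Ctsb, Ctsd, Ctsl and Npc2 with the lysosome list. It shares Lpl, Cd36, Fabp4, Fabp5 and Plin2 with the lipid uptake list. The lists, the marker genes, the tests and the rule for named genes were fixed before the data were examined. In each class the rule took the 5 rising and 5 falling genes of largest fold with adjusted p under 0.05, an average log2 CPM of at least 5 and the same direction in all 3 experiments. It also took the 2 members of smallest p from each of the 8 lists with the smallest camera p, and genes fixed by name. Predicted genes were counted but not named, and 1 further gene is not reported here. Muc16, fixed for the mesothelial-like class, had no counts there. The rule gave 116 tested values in 4 classes, 91 of them called.

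Free RNA was measured in barcodes with 1 to 50 UMIs. For each class and library, the lowest ratio of foreign marker lists set the largest amount of this profile that the class could hold, and the highest percent of a gene's UMIs it could supply was computed from that bound. Other foreign lists allowed more. The highest percents are therefore limits only if free RNA in the class has the composition of the near-empty barcodes. The bound in HFD libraries was 38.9%, 33.3% and 15.7% of UMIs in adipocyte-like, 72.6%, 51.9% and 43.7% in fibroblast or progenitor-like, 45.1%, 34.8% and 27.5% in macrophage-like and 93.6%, 55.1% and 71.0% in mesothelial-like nuclei. At LFD it was 16.6%, 24.8% and 19.8%, then 5.50%, 21.6% and 26.4%, then 6.26%, 27.0% and 38.3%, and 9.92%, 22.5% and 32.4%. As an alternative added after seeing the data, this largest amount was subtracted from every sum and the test repeated. Counting intervals are exact at 95%, and a gene with no UMI in a group was set to a floor of 3 counts over the group; both cover counting error only.

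Libraries with the same experiment number deviated together from their diet's mean: all 12 correlations between same-numbered libraries lay between 0.267 and 0.658, against -0.481 to 0.182 for the 24 between different numbers. The numbers were therefore taken to pair the libraries, and the fit with the experiment as a block is given beside a result where it changes a call. Other alternatives were no kit covariate, DESeq2, RLE factors, no filter on low counts, doublet calls kept, each library clustered on its own, another denominator, other sub-cluster resolutions of 0.8 and 0.3, each library left out, and experiments 1 and 2 alone. Nuclei with at least 1500 UMIs, cluster 0 counted as macrophage-like, the DESeq2 interaction, sub-clustering on genes scaled over all libraries, the subtraction of free RNA from 1 diet only and the rule that a sub-cluster's top 10 genes must not hold more markers of another sub-list than of its own were added after seeing the data.

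The tests were tried on simulated counts drawn from the means and sizes of the real libraries. Of 100 genes changed 2-fold, 20, 28, 23 and 27 were recovered in adipocyte-like (11038 genes), fibroblast or progenitor-like (13520 genes), macrophage-like (12924 genes) and mesothelial-like (5898 genes) sums. Of 100 changed 4-fold, 77, 78, 82 and 93 were recovered. Over both folds together, false calls numbered 11, 13, 18 and 10, with a single simulation per class. The share test recovered 17 of 100 classes changed 3-fold over 50 rounds, with 3 false calls among 450. Smaller changes can therefore be missed with these libraries. Other software was Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.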

Results

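Epididymal white adipose tissue is a visceral fat depot that lies against the epididymis in male mice. Single-nucleus RNA sequencing of this depot was used to ask which cell types make up the tissue, and how they change, when wild-type mice become obese on a high-fat diet. There were 6 libraries, 3 from mice on a low-fat diet (LFD) and 3 from mice on a high-fat diet (HFD). Experiments 1 and 2 held one library per diet each, made with the v2 kit after 18 weeks of diet. Experiment 3 held one library per diet made with the v3 kit after 22 weeks, so the kit and the duration could not be separated. The labels do not say how many mice went into a library, and the p-values below measure the spread between these libraries.

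The LFD libraries held 41136147, 60169759 and 161772042 UMIs in experiments 1, 2 and 3, and the HFD libraries held 68840817, 56232963 and 118315081. The authors' lists of nuclei named 5428, 4799 and 3971 barcodes at LFD and 5035, 4463 and 4512 at HFD. The median nucleus held 1932, 1904 and 3812 UMIs at LFD and 1837, 1569 and 3443 at HFD. Listed nuclei carried between 9.83% and 30.5% of a library's UMIs. The median mitochondrial share of the listed nuclei was 2.23%, 5.18% and 10.5% at LFD and 10.6%, 7.67% and 7.35% at HFD.

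Macrophage-like nuclei made up 14.7% ± 0.741 of kept nuclei at LFD and 50.3% ± 11.3 at HFD (SD, n = 3 libraries per diet). Their share rose in all 3 experiments, by 1.76 on the log2 scale (SE 0.22; edgeR adjusted p = 0.000988), and by 1.98 in experiments 1 and 2 alone. The size of the rise depended on cluster 0, which carried macrophage markers but stayed unnamed: counted with it, the shares were 23.6% ± 1.35 and 51.5% ± 12.5 (log2 change 1.10, SE 0.17, adjusted p = 0.00559). Adipocyte-like nuclei fell from 27.5% ± 17.3 to 8.16% ± 3.22, a log2 change of -1.61 (SE 0.36; adjusted p = 0.0145), lower at HFD in all 3 experiments. The exact two-sided permutation test of the shares gave p = 0.1 for the macrophage-like class, the smallest value it can give for 3 libraries against 3, and p = 0.2 for the adipocyte-like class. The adipocyte-like call was lost without LFD replicate 2 (log2 change -1.33, adjusted p = 0.234), without HFD replicate 1 (-1.44, adjusted p = 0.0965) and without HFD replicate 2 (-1.61, adjusted p = 0.0638). All shares are of nuclei that passed the authors' list, and nuclei of different cell types need not be recovered equally.

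Fibroblast or progenitor-like nuclei made up 32.7% ± 9.99 at LFD and 28.3% ± 11.3 at HFD. Mesothelial-like nuclei, from the lining of the depot, made up 6.59% ± 4.61 and 4.95% ± 3.92. The adjusted p was 0.674 for both. The fibroblast or progenitor-like direction turned without LFD replicate 1 (log2 change 0.05). B cell-like nuclei made up 2.16% ± 1.44 and 1.60% ± 2.25, T or NK cell-like nuclei 2.30% ± 1.13 and 1.32% ± 1.89, and endothelial-like nuclei 0.449% ± 0.436 and 0.353% ± 0.211, though with the kit as a covariate the fitted log2 change of the last was 0.21 (SE 1.12) and 2 of 3 experiments were higher at HFD. Nuclei with markers of the epididymal epithelium made up 0.391% ± 0.655 at LFD and 2.09% ± 2.45 at HFD. None of these 4 classes passed the test, and single libraries set several of these means. At LFD the B cell-like mean was 1.33% without replicate 3, the endothelial-like mean 0.225% without replicate 2, the epididymal mean 0.0127% without replicate 2 or 0.586% without replicate 1, and the mesothelial-like mean 3.93% without replicate 3. At HFD the B cell-like, T or NK cell-like and mesothelial-like means were 0.306%, 0.231% and 2.73% without replicate 3, and the epididymal mean 0.745% without replicate 1.

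Clusters 0, 9 and 13 stayed unnamed. Cluster 0 carried Cd226, Ccr2 and Clec2g among its leading genes, with 9 of 13 macrophage markers and 6 of 9 dendritic cell markers. It held 8.95% ± 2.07 of nuclei at LFD and 1.28% ± 1.23 at HFD, a log2 change of -3.34 that missed the threshold (adjusted p = 0.0596), though it was lower at HFD in all 3 experiments. That change passed without HFD replicate 2 (-4.04, adjusted p = 0.0343) and among nuclei other than adipocyte-like ones (-3.74, adjusted p = 0.023). Cluster 9, led by Dnah12 and Rgs22, held 1.23% ± 0.98 and 1.32% ± 1.81, and cluster 13, led by Dcdc2a and Adcy8, held 3.00% ± 4.07 and 0.398% ± 0.672. The fitted log2 change of cluster 9 was -0.53 (SE 2.63), against the direction of its means. Without HFD replicate 2 the HFD means of clusters 0, 9 and 13 were 0.615%, 0.288% and 0.00995%, and without LFD replicate 3 the LFD mean of cluster 13 was 0.665%.

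**Figure D1:**
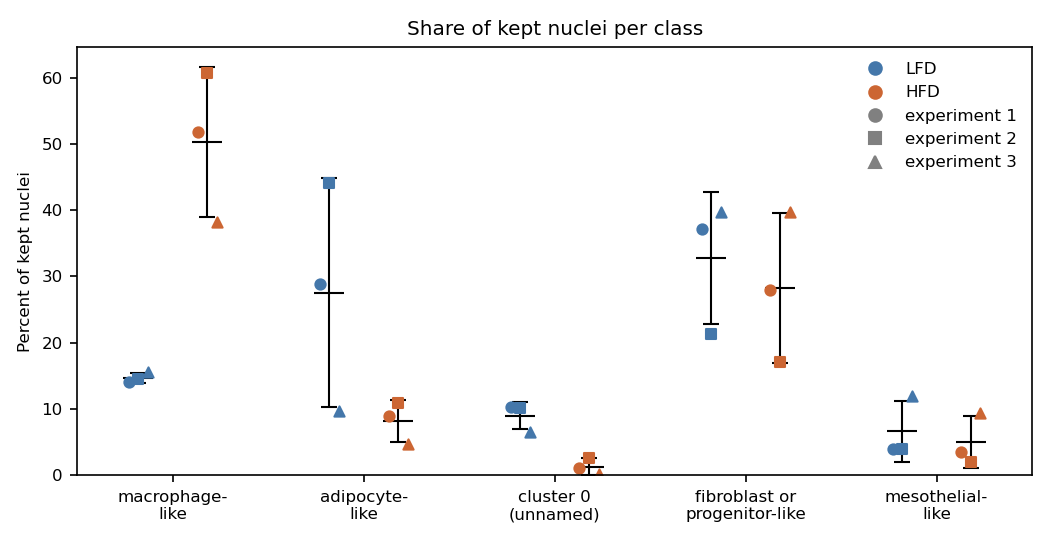
Percent of kept nuclei (y axis) in 5 classes or clusters (x axis), one point per library with the diet as colour and the experiment as shape; the horizontal mark is the mean of 3 libraries and the bar is 1 SD. The 3 HFD libraries sit above the 3 LFD libraries for macrophage-like nuclei, with means of 50.3% and 14.7%.

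In adipocyte-like nuclei, the genes of de novo lipogenesis, which build fatty acids from acetyl units, fell at HFD. Of 17 measured members, 12 fell, none rose and the rest did not pass, and the median log2 change was -1.93. Acaca (ENSMUSG00000020532, chromosome 11, 84129672 to 84401651 in mm10) encodes the acetyl-CoA carboxylase that commits acetyl units to fatty acids. It fell from 4313.5 ± 2664 to 376 ± 151 CPM (SD, n = 3), a log2 change of -3.33 (SE 0.31, edgeR adjusted p = 0.00047). CPM are UMIs scaled to the library's TMM-adjusted sum of the class. Acly, the ATP-citrate lyase, fell from 457 ± 327 to 39.9 ± 13.8 CPM, the acetyl-CoA synthetase gene Acss2 from 853 ± 522 to 125 ± 75.3, and the elongase gene Elovl6 from 171 ± 122 to 17.5 ± 9.37. Fasn, the fatty acid synthase, fell by 2.56 on the log2 scale (SE 0.46, adjusted p = 0.0254). At most 2.92% of the Acaca UMIs in an LFD library of this class could come from free RNA. Of the 12 genes that fell, 7 still did after the largest free RNA was subtracted from all libraries, with their median going from -2.46 to -2.79 (SE 0.34), and 10 did after subtraction from the LFD libraries alone (-2.24, SE 0.35).

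Over all genes, 384 rose and 170 fell among 11038 tested in adipocyte-like nuclei (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The count of 554 became 364 without LFD replicate 1, 359 without LFD replicate 2, 128 without HFD replicate 1 and 349 without HFD replicate 2. With the v2 libraries of experiments 1 and 2 alone it was 640. Without the kit as a covariate it was 93, 84 of them rising and 9 falling, and 1 lipogenic gene passed (median -2.25) and 10 lipid-associated macrophage genes. That setting ended the calls of 11 of the 21 named genes, Acly, Elovl6, Acss2, Fasn, Pcx, Mogat1, H2-Aa, Lipa, Ccl9, Cxcl12 and C3ar1, with adjusted p from 0.0514 to 0.132. Experiment 3 has 1 library per diet and no value of its own. At LFD, clusters 4, 7 and 12 held 53.7%, 36.9% and 9.08% of the class, and at HFD clusters 5 and 12 held 76.1% and 17.0%. These percents pool libraries, and the LFD clusters were nearly single libraries: 2095 of 2175 nuclei of cluster 4 came from LFD replicate 2, 1478 of 1497 of cluster 7 from LFD replicate 1 and all 368 of cluster 12 from LFD replicate 3, as all 194 of cluster 12 at HFD came from HFD replicate 3. Of the 21 named genes that were called, 13 stayed called whichever library was left out. Acly lost its call without HFD replicate 1 (adjusted p = 0.0515) and Fasn without HFD replicate 1 or HFD replicate 2, with adjusted p up to 0.138. Rnf144b, an E3 ubiquitin ligase gene, fell from 215 ± 23.2 to 17.3 ± 12.4 CPM and lost its call without HFD replicate 1 (adjusted p = 0.0939).

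Of 13 genes of triglyceride synthesis 1 fell in adipocyte-like nuclei, Mogat1 (log2 change -1.66, adjusted p = 0.0302), and Gpam was at -1.59 without passing (adjusted p = 0.121), though it passed with the experiment as a block (adjusted p = 0.00475), by DESeq2, with no filter on low counts and without LFD replicate 2. Of 19 genes of the citrate cycle and branched-chain amino acid breakdown 1 fell, Pcx, which encodes pyruvate carboxylase (-1.12, adjusted p = 0.0188), while Sdha was at -0.57 (adjusted p = 0.136). Leaving out any one library of experiments 1 and 2 ended the calls of both Mogat1 and Pcx, with adjusted p up to 0.237 and 0.215. Of the adipocyte genes named in advance, Adipoq was at -0.42 (adjusted p = 0.722), Lep at 0.05 (adjusted p = 0.946), Plin1 at -0.69 (adjusted p = 0.125), Pparg at -0.40 (adjusted p = 0.771) and Insr at -0.36 (adjusted p = 0.422). Plin1 passed with no filter on low counts, and Pparg passed, lower at HFD, when either or both libraries of experiment 3 were left out.

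The genes that rose most in adipocyte-like nuclei included Nhs (ENSMUSG00000059493, chromosome X, 161833296 to 162159730), from 3.00 ± 1.39 to 129 ± 76.6 CPM (log2 change 5.46, SE 0.57, adjusted p = 0.00289), and the potassium channel gene Kcnc2, from 4.38 ± 3.58 to 161 ± 49.7 (5.41, SE 0.56, adjusted p = 0.00322). Free RNA could supply at most 3.02% and 2.31% of their UMIs in an HFD library. Genes of lipid-associated macrophages, a list of markers of macrophages that take up lipid, rose in 15 of 23 members with a median of 1.79, among them Gpnmb (2.66 ± 1.18 to 159 ± 80.8), the lipid receptor gene Trem2 (2.94 ± 0.538 to 119 ± 16.7) and Lgals3 (58.7 ± 12.7 to 678 ± 138). Free RNA could supply up to 82.1%, 75.0% and 62.6% of the UMIs of these 3 genes in an HFD library. The macrophage marker list stood at 4.42%, 4.93% and 10.4% of its level in macrophage-like nuclei at LFD, and at 26.7%, 17.2% and 23.8% at HFD. Part of that difference was the macrophage-like level itself, which was 19292, 11459 and 12120 CPM at LFD and 5304, 8737 and 8901 at HFD in experiments 1, 2 and 3, while the list in adipocyte-like nuclei was at 853, 565 and 1258 CPM at LFD and 1416, 1507 and 2122 at HFD.

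Of 7 genes of antigen presentation on class II 6 rose in adipocyte-like nuclei, H2-Aa by a log2 change of 1.21. Of 21 lysosomal genes 6 rose, with Ctsl at 1.79. Of 13 chemokines and cytokines 3 rose, with Ccl9 at 1.42 and Cxcl12 at 2.20. Of 12 complement genes 1 rose, C3ar1 at 2.68, with Serping1 at 0.91 (adjusted p = 0.0529), which passed by DESeq2 and with no filter on low counts. H2-Aa lost its call without HFD replicate 1 (adjusted p = 0.0629), Cxcl12 without LFD replicate 2 or HFD replicate 1 (up to 0.114) and C3ar1 without LFD replicate 1 or HFD replicate 1 (up to 0.068). Without the kit as a covariate 1 class II gene and 2 lysosomal genes rose, with 0 chemokines and cytokines and 0 complement genes. Of all 384 genes that rose, free RNA could supply over 50% of the UMIs of 171 in an HFD library. Of the 170 that fell, it could do so for 5 in an LFD library. Crisp1, which encodes a secreted protein of the epididymis, had 1 UMI at LFD and 493 at HFD, a ratio of 1528 (95% counting interval 273 to 60477). Up to 43.9% could come from free RNA under the bound of the lowest foreign list. The epididymal list alone allowed 79.7%, 55.7% and 66.3% of the near-empty profile in HFD replicates 1, 2 and 3. After subtraction of the largest amount of free RNA that the markers allow, 155 genes were called, 145 of them also called before and in the same direction.

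With a preset correlation, camera called 12 of 31 lists in adipocyte-like nuclei, led by lipogenesis (adjusted p = 7.2e-19) and the lipid-associated macrophage genes (adjusted p = 3.7e-18). None was called with an estimated correlation, where the adjusted p was 0.382 for both lists. The adjusted p was 4.2e-08 for class II, 2.0e-07 for the lysosome, 0.000115 for chemokines and cytokines and 0.000316 for the citrate cycle list, and 0.426 for each of the 4 with an estimated correlation. Complement had 0.00164 and triglyceride synthesis 0.00177, against an adjusted p = 0.426 and an adjusted p = 0.433 with an estimated correlation. By fry, only the lipogenesis and lipid-associated macrophage lists passed (adjusted p = 0.0445 for both; with the experiment as a block, 0.139 for both). With the experiment as a block camera also called the circadian clock list (adjusted p = 0.0118), in which Npas2 alone fell. Adjusted over the list alone, 14 lipogenic genes fell, 17 lipid-associated macrophage genes rose and 1 fell. On that basis 6 class II genes, 9 lysosomal genes and 6 chemokines and cytokines rose, 6 complement genes rose and 1 fell, and 1 gene each of the citrate cycle and triglyceride lists fell.

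In macrophage-like nuclei, genes of lipid-associated macrophages rose at HFD and genes of tissue-resident macrophages fell. The unnamed cluster 0, with 9 of 13 macrophage markers, was not part of these sums. It held 1295 nuclei at LFD and 176 at HFD, against 2064 and 7010 macrophage-like ones. Genes were not tested with cluster 0 added, so the size of these changes may depend on leaving it out. Of 23 lipid-associated genes 21 rose and none fell, with a median log2 change of 2.10. Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147 in mm10) rose from 26.7 ± 13.8 to 504 ± 207 CPM (SD, n = 3; log2 change 4.36, SE 0.30, edgeR adjusted p = 0.000261), and Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, from 13.5 ± 5.13 to 351 ± 59.4. Itgax, which encodes CD11c, rose from 7.52 ± 4.21 to 87.2 ± 17.7, and the tetraspanin gene Cd9 from 60.4 ± 9.02 to 399.9 ± 119. Of 16 resident macrophage genes 11 fell and none rose, with a median of -1.58. Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), a receptor for phosphatidylserine, fell from 70.7 ± 9.25 to 2.93 ± 0.837 (log2 change -4.56, SE 0.27, adjusted p = 0.000222).

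The resident genes that fell also included Lyve1, a hyaluronan receptor gene, from 197 ± 30.7 to 16.1 ± 10.4 CPM, the haemoglobin scavenger receptor gene Cd163 from 605 ± 304 to 139 ± 111, and the mannose receptor gene Mrc1 from 1549 ± 204 to 606 ± 225. Mrc1 lost its call without HFD replicate 2 (adjusted p = 0.0508). Among the 5 largest falls were Cd209d, Cd209g and Cd209b, C-type lectin genes at -4.42, -4.26 and -3.94, and the interferon-inducible Ifi202b at -4.09. Members of these families resemble each other and their reads may have been divided between copies, so single values are uncertain. Ccr2, a chemokine receptor of monocytes, was at -0.40 (adjusted p = 0.596).

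Of 22 lysosomal genes 14 rose in macrophage-like nuclei, with Lipa, the lysosomal acid lipase, from 92.7 ± 23.5 to 489 ± 13.8 CPM and Atp6v1a at a log2 change of 1.46. Lipa, Ctsb, Ctsd, Ctsl and Npc2, which all rose, are also counted among the lipid-associated genes. Of 24 cell division genes 12 rose, with the kinetochore gene Knl1 at 2.68 (1.53 ± 0.581 to 10.9 ± 6.91) and Diaph3 at 1.77. Knl1 lost its call without LFD replicate 1 (adjusted p = 0.0514) and was not tested without HFD replicate 1 or HFD replicate 2, where it did not pass the filter on low counts. Diaph3 lost its call without LFD replicate 1 or LFD replicate 2, with adjusted p up to 0.0564. Of 17 genes of lipid uptake 7 rose and 1 fell, with the lipid droplet gene Plin2 at 1.82, the receptor gene Lrp1 at 1.33 and the lipoprotein lipase gene Lpl at 1.41 (adjusted p = 0.0477). The Lpl call was lost without any one of the 6 libraries, with adjusted p up to 0.167. Free RNA could supply up to 24.96% of the Plin2 UMIs and 26.4% of the Lpl UMIs in an HFD library.

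Of 17 lipogenic genes 8 fell in macrophage-like nuclei, with Acss2 at -1.91 and Acaca at -1.49. Up to 80.8% and 71.9% of their UMIs in an LFD library could come from free RNA. Of 18 genes of insulin signalling 1 rose, Pik3cb at 1.63, and 4 fell, with Insr at -1.03. Pik3cb lost its call without LFD replicate 3 or HFD replicate 3, with adjusted p up to 0.0632. Of 15 interferon response genes 2 fell, Oas2 at -1.74 and Parp14 at -0.88, and the Parp14 call was lost without any one of the 6 libraries (adjusted p up to 0.124). Among the 5 largest rises, Myh15 had 2 UMIs at LFD and 1225 at HFD, a ratio of 157 (95% counting interval 43.4 to 1298), with up to 4.68% from free RNA. Crisp1, Defb28, Defb22 and Wfdc10, which encode secreted proteins of the epididymis, made up the other 4. Crisp1, Defb28 and Defb22 had no UMI at LFD and were at least 211-, 182- and 75.4-fold higher at HFD against a floor of 3 UMIs over the 3 LFD libraries. Wfdc10 had 2 UMIs at LFD and 1319 at HFD. Under the bound of the lowest foreign list, free RNA could supply up to 39.9% to 43.7% of their UMIs in an HFD library. The epididymal list alone allowed 105%, 65.6% and 38.1% of the near-empty profile in HFD replicates 1, 2 and 3. The remainder of these UMIs is thus not shown to be expression in macrophages.

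Over all genes, 703 rose and 614 fell among 12924 tested in macrophage-like nuclei. The count of 1317 became 873 without LFD replicate 2, 657 without LFD replicate 3, 764 without HFD replicate 1, 765 without HFD replicate 2, 668 without HFD replicate 3 and 618 in experiments 1 and 2 alone. Without the kit as a covariate it was 505. In that fit 13 lipid-associated, 6 lysosomal, 2 lipid uptake and 1 cell division genes rose, and 6 resident and 3 lipogenic genes fell. No insulin signalling or interferon response gene passed. The calls of 14 of the 30 named genes were then lost, those of Crisp1, Defb28, Defb22, Ifi202b, Cd163, Mrc1, Knl1, Diaph3, Acaca, Insr, Pik3cb, Oas2, Parp14 and Lpl, with adjusted p from 0.0523 to 0.164. Of the 30 named genes that were called, 24 stayed called whichever library was left out. At LFD, clusters 1 and 17 held 63.1% and 30.04% of the class, and at HFD clusters 15, 17, 18 and 20 held 66.3%, 16.0%, 8.03% and 5.15%, pooled over libraries. Experiment 3 supplied 594 of 620 nuclei of cluster 17 at LFD, 1118 of 1122 at HFD and 561 of 563 nuclei of cluster 18 at HFD. With the largest free RNA subtracted, 526 genes were called, 511 of them as before. Of the 21 lipid-associated genes that rose 3 were still called, and their median went from 2.20 to 3.93 as its SE grew to 1.18. With the subtraction from the HFD libraries alone, 19 of the 21 were still called. The sums were scaled anew after it, and the median of the 21 was 2.40 (SE 0.30), above the 2.20 before. It is therefore not a lower limit of the rise.

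In macrophage-like nuclei camera called 14 lists, with an adjusted p of 4.4e-23 for lipid-associated, 3.1e-12 for resident, 1.4e-11 for lysosomal and 1.1e-10 for cell division genes. With an estimated correlation no list was called. The lipid-associated and lysosomal lists had an adjusted p = 0.382, the resident list an adjusted p = 0.426 and the cell division list an adjusted p = 0.433. Lipogenesis had 6.3e-08, lipid uptake 0.000657, insulin signalling 0.00328 and interferon response 0.00725. With an estimated correlation these had an adjusted p = 0.426, an adjusted p = 0.433, an adjusted p = 0.411 and an adjusted p = 0.433. By fry, the lipid-associated, lysosomal and circadian clock lists passed (adjusted p = 0.0445, 0.0445 and 0.0456); with the experiment as a block only the lipid-associated list did (adjusted p = 0.0169). Adjusted over the list alone, 22 lipid-associated genes, 16 lysosomal and 21 cell division genes rose, 13 resident and 12 lipogenic genes fell, 8 lipid uptake genes rose and 1 fell, 1 insulin signalling gene rose and 6 fell, and 3 interferon response genes fell.

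In fibroblast or progenitor-like nuclei, 3 of 13 early progenitor genes fell at HFD, and 15 of 23 lipid-associated macrophage genes rose. The early progenitor genes that fell included Efhd1 from 185 ± 52.6 to 78.4 ± 4.01 CPM (SD, n = 3; log2 change -1.23, SE 0.21, edgeR adjusted p = 0.0089) and Opcml, an adhesion molecule gene, from 889.9 ± 57.2 to 455 ± 81.5 (-0.98, SE 0.18, adjusted p = 0.0141). Dpp4 was at -0.58 (adjusted p = 0.136, passing with no filter on low counts) and Pi16 at -0.11 (adjusted p = 0.899). The largest falls were Rtl4 at -1.90, Cadps, which encodes a regulator of vesicle release, at -1.89, the estrogen sulfotransferase gene Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594) at -1.65, Fyb2 at -1.52 and Ildr2 at -1.50, and free RNA could supply at most 7.11% of the UMIs of any of these 5 in an LFD library. Icam1, an adhesion molecule gene, rose from 10.2 ± 1.36 to 30.2 ± 11.7 (1.41, SE 0.30, adjusted p = 0.0258), with up to 13.6% from free RNA. Rtl4 lost its call without HFD replicate 2 (adjusted p = 0.0558), Ildr2 without HFD replicate 1 or 2 (up to 0.0851) and Sult1e1 without LFD replicate 2, HFD replicate 1 or HFD replicate 2 (up to 0.16).

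Of 23 lipid-associated macrophage genes 15 rose in fibroblast or progenitor-like nuclei, with a median of 2.05, Trem2 at 5.69 and Lgals3 at 3.92. Of 22 lysosomal genes 9 rose, with Ctsb at 1.86 and Ctsd at 2.07. Of 10 class II genes 6 rose, with Ctss at 3.25 and H2-Aa at 1.69. Of 18 chemokines and cytokines 4 rose, with Ccl9 at 1.84 and Ccl6 at 1.33. Of 17 cell division genes 2 rose, Cdk1 at 2.70 and Smc2 at 1.34, and of 17 lipid uptake genes 4 rose, with Apoe at 1.83 and Angptl4, an inhibitor of lipoprotein lipase, at 2.12. Free RNA could supply up to 83.8% of the Trem2 UMIs, 72.6% of the Ctss UMIs, 87.3% of the Cdk1 UMIs and 45.7% of the Angptl4 UMIs in an HFD library. The macrophage marker list stood at 5.30%, 6.38% and 11.4% of its level in macrophage-like nuclei at LFD, and at 43.4%, 23.6% and 39.4% at HFD. Since that level was lower at HFD, the list's own CPM differed less, at 1023, 731 and 1386 at LFD and 2300.2, 2058 and 3504 at HFD. Defb28, Crisp1 and Wfdc10, made by the epididymis, had 1, 3 and 3 UMIs at LFD against 926, 1135 and 568 at HFD, ratios of 1170 (95% counting interval 209 to 46263), 478 (163 to 2321) and 239 (81.4 to 1164). Without single libraries the calls of Ctsd and Cdk1 (LFD replicate 3, HFD replicate 1 or HFD replicate 3; adjusted p up to 0.0779 and 0.134), Angptl4 (LFD replicate 2, HFD replicate 1 or HFD replicate 2; up to 0.0897), Wfdc10 (any library of experiments 1 and 2; up to 0.172) and Smc2 (any library but LFD replicate 2; up to 0.145) were lost.

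Of 17 lipogenic genes 4 fell in fibroblast or progenitor-like nuclei, with Scd2 at -1.34 and Acaca at -1.06, where free RNA could supply up to 37.8% and 60.8% of the UMIs in an LFD library. Acaca lost its call without HFD replicate 1 or 2 (adjusted p up to 0.0633). Col1a1 was at 0.78 (adjusted p = 0.0775, passing by DESeq2, with no filter on low counts and with genes free RNA could supply left out), Pdgfra at -0.50 (adjusted p = 0.289) and Fn1 at -0.16 (adjusted p = 0.874). Over all genes 376 rose and 102 fell among 13520 tested. Of the 376, free RNA could supply over 50% of the UMIs of 286 in an HFD library, and of the 102 it could do so for 8 in an LFD library. The count of 478 became 10 with the largest free RNA subtracted, 2 of them called before in the same direction. It became 310 without LFD replicate 1, 161 without HFD replicate 1, 306 without HFD replicate 2 and 349 in experiments 1 and 2 alone. Without the kit as a covariate it was 72, 71 of them rising and 1 falling, and the calls of the 3 early progenitor genes and the 4 lipogenic genes were all lost while 8 lipid-associated macrophage genes rose. Of the other lists 1 lysosomal and 3 class II genes rose in that setting, and no gene for chemokines and cytokines, cell division or lipid uptake. Of the 25 named genes only Trem2, Lgals3, Ctsb, Ctss and H2-Aa stayed called without the kit. The adjusted p of the other 20 ran from 0.0578 to 0.519. Of the 25 named genes that were called, 13 stayed called whichever library was left out. Efhd1 lost its call without HFD replicate 1 or 2 (adjusted p up to 0.0793), and Opcml without LFD replicate 2, HFD replicate 1 or HFD replicate 2 (up to 0.0951). Icam1 lost its call without any one library of experiments 1 and 2 (up to 0.139). At LFD, clusters 2 and 3 held 60.02% and 36.6% of the class, and at HFD clusters 6, 3 and 2 held 66.0%, 23.6% and 10.4%.

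In this class camera called 16 lists, and none with an estimated correlation. The adjusted p was 1.4e-26 for lipid-associated macrophage genes and 2.3e-05 for cell division (adjusted p = 0.382 for both with an estimated correlation). It was 3.1e-12 for the lysosome, 3.8e-11 for lipogenesis, 3.7e-09 for class II, 3.8e-08 for early progenitor genes and 0.00074 for chemokines and cytokines, and each of these 5 had an adjusted p = 0.426 with an estimated correlation. Lipid uptake had 3.8e-05, with an adjusted p = 0.466 with an estimated correlation. By fry, the lipid-associated list alone passed (adjusted p = 0.0445; with the experiment as a block, 0.139). The ribosomal protein list, with no member past the threshold, was called by camera (adjusted p = 0.045; adjusted p = 0.757 with an estimated correlation) but not with the experiment as a block (adjusted p = 0.067). Adjusted over the list alone, 19 lipid-associated, 14 lysosomal, 7 class II and 7 cell division genes rose. On that basis 9 early progenitor and 8 lipogenic genes fell, 8 lipid uptake genes rose and 1 fell, and 7 chemokines and cytokines rose and 1 fell.

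In mesothelial-like nuclei nearly all called genes rose: 97 rose and 4 fell among 5898 tested. The genes that fell were Adam23 (ENSMUSG00000025964, chromosome 1, 63445891 to 63596276 in mm10), from 247 ± 54.8 to 69.9 ± 10.1 CPM (SD, n = 3; log2 change -1.78, SE 0.27, edgeR adjusted p = 0.00142), Acaca at -1.25, the growth arrest gene Gas1 at -1.24 and the thrombomodulin gene Thbd at -1.13. Adam23 kept its call whichever library was left out. Acaca lost it without any library but LFD replicate 1, and Gas1 and Thbd lost it without LFD replicate 3, HFD replicate 1 or HFD replicate 3, with adjusted p up to 0.272, 0.121 and 0.314. Of 12 mesothelial identity genes none passed, with a median of -0.61. Upk3b was at -1.12 (adjusted p = 0.0514) and Krt19 at -1.19 (adjusted p = 0.134), and both passed with the experiment as a block (adjusted p = 0.00765 and 0.00548) and with no filter on low counts. Upk3b also passed by DESeq2 and with genes free RNA could supply left out. Msln and Wt1 were both at -0.29 (adjusted p = 0.816 and 0.799) and Cfb at 0.41 (adjusted p = 0.743).

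Of 23 lipid-associated macrophage genes 14 rose in mesothelial-like nuclei, with a median of 1.90, among them Gpnmb at 4.72, the signalling adaptor gene Tyrobp at 2.78, and Atp6v0d2, with 1 UMI at LFD and 152 at HFD, a ratio of 213 (95% counting interval 37.6 to 8458). Mmp12, the macrophage metalloelastase, rose from 10.9 ± 7.48 to 438 ± 286 CPM, Cd300c2 by a log2 change of 3.42 and Mpeg1 by 3.20. Of 17 lysosomal genes 7 rose, with Lipa at 2.31 and Ctsz at 1.76, and of 7 class II genes 5 rose, with Ctss at 2.64 and H2-Aa at 1.56. Of 14 lipid uptake genes 1 rose, Cd36 at 1.57, and Plin2, at 1.82, missed the threshold (adjusted p = 0.0583) but passed with the experiment as a block (adjusted p = 0.00596), by DESeq2, with no filter on low counts, with nuclei of at least 1500 UMIs, with the highest doublet scores removed and without LFD replicate 2. Of the 97 genes that rose, free RNA could supply over 50% of the UMIs of 93 in an HFD library. Cd300c2 and H2-Aa lost their calls without LFD replicate 3 or HFD replicate 3 (adjusted p up to 0.291 and 0.0891), Ctsz without HFD replicate 3 (0.0561) and Cd36 without LFD replicate 1, LFD replicate 3, HFD replicate 1 or HFD replicate 3 (up to 0.29). The macrophage marker list stood at 15.6%, 11.7% and 14.03% of its level in macrophage-like nuclei at LFD, and at 69.2%, 33.5% and 46.5% at HFD. Since that level was lower at HFD, the list's own CPM differed less, at 3009, 1345 and 1701 at LFD and 3672, 2926 and 4139 at HFD.

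Without the kit as a covariate, mesothelial-like nuclei lost the calls of Acaca, Gas1, Thbd, Tyrobp, H2-Aa and Cd36, with adjusted p from 0.0504 to 0.625. In that fit 8 lipid-associated, 3 lysosomal and 1 class II genes rose. The count of 101 genes became 24 in that setting, 202 with the experiment as a block, 44 without LFD replicate 3, 49 without HFD replicate 1, 34 without HFD replicate 3, 37 in experiments 1 and 2 alone, and 8 with the largest free RNA subtracted, 0 of them among the 101. Cluster 8 held the class at both diets. Of 14 lipogenic genes 1 fell, Acaca, and Acss2, at -1.58, missed the threshold (adjusted p = 0.0778; with the experiment as a block, 0.0238) but also passed with no filter on low counts, with doublet calls kept and without HFD replicate 2. Of 19 ribosomal protein genes none passed, with Rpl19 at 0.77 (adjusted p = 0.268; with the experiment as a block, 0.0491) and Rpl37 at 0.67 (adjusted p = 0.336). None of 10 early progenitor genes passed, with Opcml at -0.76 (adjusted p = 0.326) and Cd34 at -0.71 (adjusted p = 0.407).

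Of 29 lists tested in mesothelial-like nuclei camera called 10, and none with an estimated correlation. The adjusted p was 2.1e-34 for lipid-associated macrophage genes, 2.7e-16 for the lysosome, 7.0e-12 for class II and 0.00102 for early progenitor genes, each with an adjusted p = 0.382 with an estimated correlation. Lipogenesis had 4.1e-07, mesothelial identity 2.3e-06, lipid uptake 7.6e-05 and ribosomal proteins 0.000657. With an estimated correlation these had an adjusted p = 0.466, an adjusted p = 0.433, an adjusted p = 0.491 and an adjusted p = 0.588. By fry, the lipid-associated and lysosomal lists passed (adjusted p = 0.0445 for both), and none did with the experiment as a block (lowest adjusted p = 0.139). Adjusted over the list alone, 20 lipid-associated, 11 lysosomal, 7 class II and 6 lipid uptake genes rose, 6 lipogenic and 3 mesothelial identity genes fell, and 0 ribosomal or early progenitor genes passed.

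**Figure D2:**
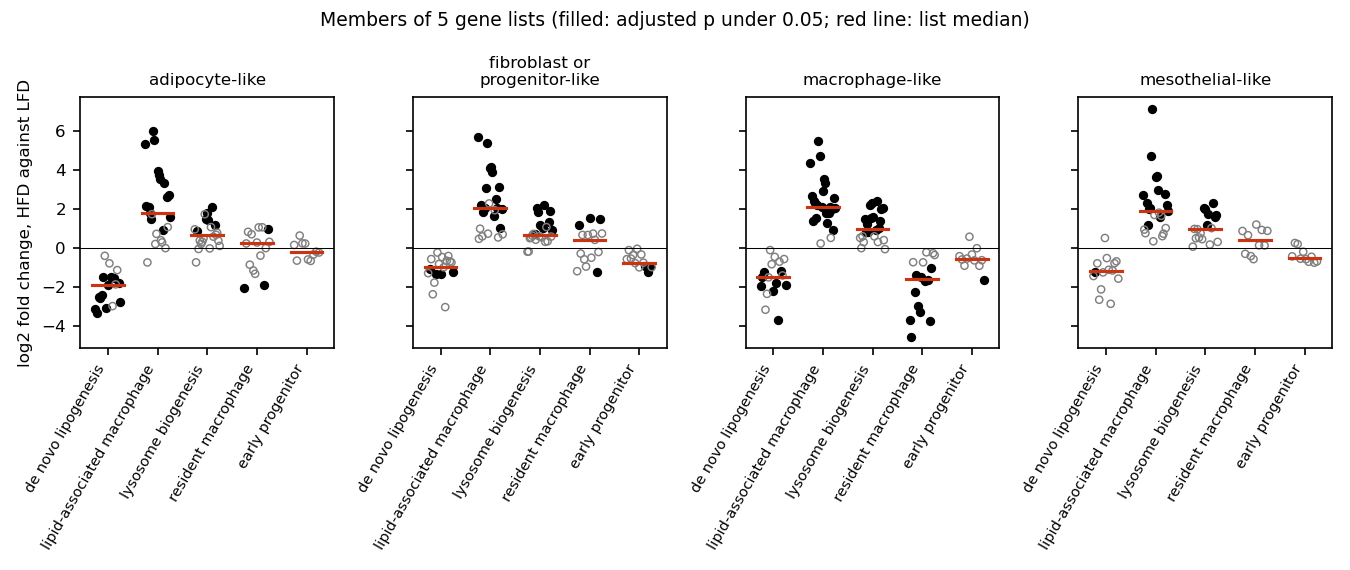
Log2 fold change at HFD against LFD (y axis) of each measured member of 5 gene lists (x axis) in 4 classes (panels); filled points have an edgeR adjusted p under 0.05, open points do not, and the red line is the list's median. The lipogenic medians lie below 0 in all 4 panels, at -1.93 in adipocyte-like nuclei, and the lipid-associated macrophage medians lie above 0, at 2.10 in macrophage-like nuclei.

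Within the fibroblast or progenitor-like class, early progenitor-like nuclei, a sub-cluster with 8 of 9 early progenitor markers, fell from 42.1% ± 3.71 of the class at LFD to 27.8% ± 1.27 at HFD (SD, n = 3; log2 change -0.61, SE 0.11, edgeR adjusted p = 0.000732), lower in all 3 experiments. The exact permutation test gave p = 0.1, the smallest it can give. The call was lost without HFD replicate 2 (-0.63, adjusted p = 0.0507) and with genes scaled over all libraries (-0.84, adjusted p = 0.0961). Sub-cluster 0 of this class, with Pde11a and Fgf10 among its top 10 genes by fold, rose from 49.1% ± 3.64 to 61.6% ± 1.86 (0.33, adjusted p = 0.0108; with the experiment as a block, adjusted p = 0.0812). Without LFD replicate 3, HFD replicate 1, HFD replicate 2 or HFD replicate 3 its call was lost too, with log2 changes from 0.29 to 0.38. Sub-cluster 2, with Ccl2, Ccl7 and Tnc among its top 10, held 1.69% ± 0.459 and 3.49% ± 0.548 (adjusted p = 0.0518).

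Within the macrophage-like class, sub-cluster 3, led by Chst11, Mmp12 and Dcstamp, rose from 3.78% ± 1.96 to 13.7% ± 1.40 (SD, n = 3; log2 change 1.97, SE 0.54, edgeR adjusted p = 0.0108). With the experiment as a block the adjusted p was 0.0812, and the call was lost without HFD replicate 2 (2.06, adjusted p = 0.166) and without HFD replicate 3 (1.56, adjusted p = 0.0512). It carried 5 of 10 cell division markers, but none among its top 10 genes by fold, and stayed unnamed. Other clusterings gave smaller sub-clusters with 9 or 10 of these markers, which were named dividing cell-like and were higher at HFD in all 3 experiments. They held 2.24% ± 1.26 and 6.31% ± 3.86 at resolution 0.8 (log2 change 1.43, adjusted p = 0.00314, exact permutation p = 0.3) and 1.38% ± 0.997 and 5.48% ± 3.45 at resolution 0.3 (1.97, adjusted p = 0.00421, exact permutation p = 0.2). With genes scaled over all libraries they held 0.539% ± 0.598 and 6.25% ± 5.37 (3.59, adjusted p = 0.165, exact permutation p = 0.3), and with the genes called between diets included 0.775% ± 0.831 and 5.09% ± 3.48 (2.68, adjusted p = 0.00493, exact permutation p = 0.2).

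In that last clustering, genes that differ between diets help to set the sub-clusters of macrophage-like nuclei. A lipid-associated macrophage-like sub-cluster, with 6 of 10 markers, went from 12.1% ± 1.76 to 35.2% ± 1.15 (SD, n = 3; edgeR adjusted p = 1.7e-07, exact permutation p = 0.1). A perivascular or resident macrophage-like sub-cluster, with 10 of 10 markers, held no nucleus at LFD and 6.52% ± 4.00 at HFD (edgeR adjusted p = 1.4e-05, exact permutation p = 0.1). Counting error alone allows up to 0.394%, 0.434% and 0.491% in the 3 LFD libraries. Genes were scaled within each library, so nuclei stand out only against others of their library. The empty sub-cluster therefore does not show that resident macrophages were absent at LFD. In the joint clustering, clusters 1 and 17, with 10 of 10 resident markers, held 63.1% and 30.04% of the class at LFD. At HFD clusters 17 and 19, also with 10 of 10, held 16.0% and 4.07%. The unnamed sub-cluster 2, with 2 of these 10 markers, went from 63.1% ± 2.74 to 35.3% ± 3.91 (adjusted p = 2.3e-06, exact permutation p = 0.1). A sub-cluster of the resident name held 95.9% ± 3.35 and 94.3% ± 3.58 at resolution 0.3 (adjusted p = 0.611), and 27.6% ± 46.9 and 0.803% ± 1.11 with genes scaled over all libraries (adjusted p = 0.321).

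Sub-cluster 5 of macrophage-like nuclei, led by Alox15, Prg4 and Ltbp1, fell from 2.79% ± 3.05 to 0.195% ± 0.138 (-3.59, adjusted p = 0.0108; with the experiment as a block, adjusted p = 0.0859), though it was higher at HFD in 1 of 3 experiments and the exact permutation test gave p = 0.4. That call was lost without LFD replicate 1 (-2.65), HFD replicate 1 (-3.16) or HFD replicate 2 (-3.58). The LFD mean of this sub-cluster rested mainly on LFD replicate 1, with 46, 16 and 0 nuclei in LFD replicates 1, 2 and 3. Within the adipocyte-like class, sub-cluster 1, led by Tfeb, rose from 18.1% ± 2.59 to 24.7% ± 2.73 (0.46, adjusted p = 0.0431; with the experiment as a block, adjusted p = 0.0812) and lost its call without LFD replicate 3, HFD replicate 1, HFD replicate 2 or HFD replicate 3, with log2 changes from 0.41 to 0.53. Sub-cluster 3, with the lipogenic genes Acss2, Acly and Elovl6 among its top 10 but none of 8 lipogenic markers past the naming bound, held 37.9% ± 9.08 and 29.5% ± 1.38 (-0.37, adjusted p = 0.0518), and passed without LFD replicate 1 (-0.23, adjusted p = 0.0349) or LFD replicate 2 (-0.55, adjusted p = 0.0156).

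**Figure D3:**
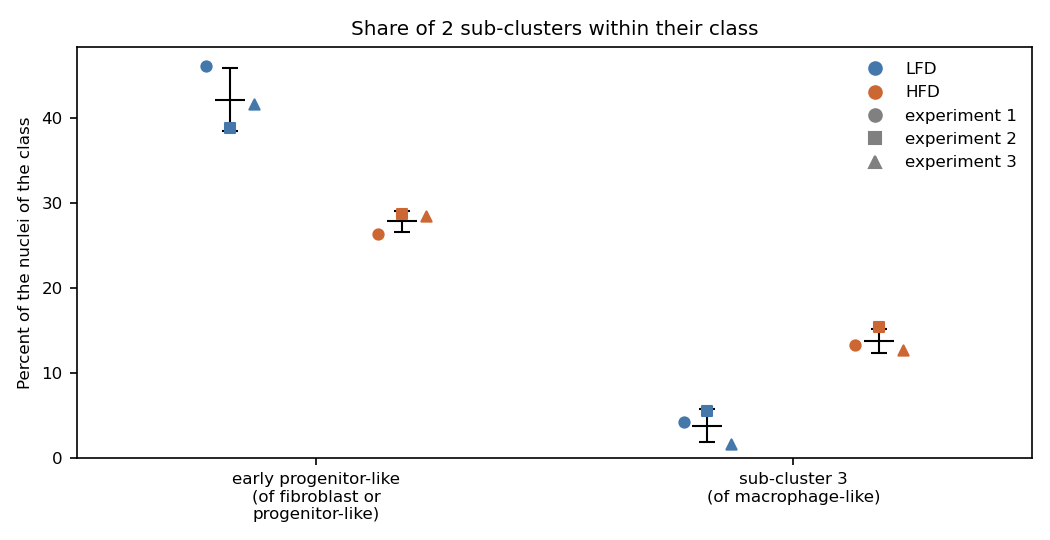
Percent of the nuclei of the class (y axis) in 2 sub-clusters (x axis), one point per library with the diet as colour and the experiment as shape; the horizontal mark is the mean of 3 libraries and the bar is 1 SD. Early progenitor-like nuclei average 42.1% at LFD and 27.8% at HFD, and sub-cluster 3 of macrophage-like nuclei 3.78% and 13.7%.

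Whether the diet effect differed after 22 weeks from that after 18 weeks was tested with an interaction, which rests on 1 library per diet at 22 weeks and is confounded with the kit. For single genes edgeR called 0 in each of the 4 classes, with 640, 814, 494 and 89 genes at an unadjusted p under 0.05 in adipocyte-like, fibroblast or progenitor-like, macrophage-like and mesothelial-like nuclei. DESeq2 called 13, 5, 9 and 0 in the same order, with 293, 279, 187 and 25 at an unadjusted p under 0.05. Its adjustment covered fewer genes in the first 2 classes, where 8132 of 11038 and 9436 of 13520 genes received no adjusted p. Of the class shares edgeR called none, with a lowest adjusted p of 0.185, for clusters 9 and 13. The difference in macrophage-like share, HFD minus LFD, was 37.7 and 46.3 percentage points in experiments 1 and 2 and 22.8 in experiment 3.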

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

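Tests chosen only after the data were seen were those for doublets, for less adipocyte RNA per nucleus and for both explanations of the macrophage-like share. So were sub-clusters built with the called genes included, the DESeq2 interaction, the other splits of the libraries and every subtraction of free RNA. Bounds were written before the results for the subtraction from all libraries, for one shared source and for sub-clusters built without the called genes. The readings below also use a margin for spread and, for the subtraction, a condition on the median, which those written bounds did not hold. By count alone, 0 of 15 and 0 of 14 lipid-associated macrophage genes (fibroblast or progenitor-like, mesothelial-like) and 3 of 8 lipogenic genes (macrophage-like) lay below the bound. In adipocyte-like nuclei 8 of 15 lay above it.

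Genes of lipid-associated macrophages rose in adipocyte-like, fibroblast or progenitor-like and mesothelial-like nuclei as well as in macrophage-like ones. Droplets with a macrophage nucleus as well stay open as a cause in adipocyte-like nuclei. Their test used the spread of the macrophage marker list over nuclei, not that of the lipid-associated genes. That list already stood at 853, 565 and 1258 CPM at LFD, against 1416, 1507 and 2122 at HFD. In HFD libraries, nuclei at or above 0.25 of the macrophage-like level held at most 5.47 percentage points more macrophage-list UMIs than an even spread. The even spread itself was 70.7%, 31.4% and 52.3% in HFD replicates 1, 2 and 3, which left little room for an excess in replicate 1. There the class as a whole, at 26.7% of the macrophage-like level, already lay above the cut. The excess of 2.39 in fibroblast or progenitor-like nuclei leaves doublets open, since the even spread already reached 93.5% and 95.5% in HFD replicates 1 and 3. Free RNA cannot be told apart from expression in the cells for the genes as a set: after the largest subtraction from all libraries 8 of 15 members still rose in adipocyte-like nuclei, a margin over the bound below its spread, with a median that went from 2.70 to 8.04 (SE 1.04) and rests on 9 members left with no UMI at LFD, and 0 of 15 and 0 of 14 in the other classes, where the median went from 2.49 to 3.39 (SE 1.75) and from 2.52 to 3.6 (SE 1.91) and calls ended as the error grew. With the subtraction from HFD alone, after which the sums were scaled anew, 7 of 15, 1 of 15 and 0 of 14 still rose. The medians over all members that rose before were 2.30 (SE 0.38), 1.96 (SE 0.49) and 1.91 (SE 0.53). The amount was set by the lowest foreign list, at 38.9%, 33.3% and 15.7% of UMIs in the adipocyte-like HFD sums. The macrophage list alone allowed 46.2%, 51.0% and 51.9% there. That larger amount was not subtracted, so the 7 remaining calls do not settle free RNA. A change of expression with diet in these cells is an untested hypothesis, and one source shared by both classes stays open too, since the SD of the log2 ratios between adipocyte-like and fibroblast or progenitor-like nuclei was 0.62, 0.82 and 0.79 in the HFD libraries, between the bounds set for one source and for separate ones.

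Lipogenic genes fell in adipocyte-like nuclei by a median log2 change of -1.93 and in macrophage-like nuclei by -1.49. Adipocyte markers outside the list had a median of -0.17 (SE of the mean 0.13) in adipocyte-like nuclei, so the lipogenic genes fell more than these. Less adipocyte RNA per nucleus stays open, since CPM are shares of a sum and the same markers helped to name the class. A shift between sub-clusters cannot be told apart from a fall within them. With the called genes included a lipogenic adipocyte-like sub-cluster went from 14.1% ± 9.42 at LFD to 2.38% ± 0.847 at HFD (log2 change -2.61, edgeR adjusted p = 4.7e-05). Within the 3 other sub-clusters large enough to test the median change was -1.79 (SE 0.33), -1.92 (SE 0.48) and -1.93 (SE 0.40). Genes were scaled within each library, however, so a fall shared by a library's nuclei is removed before clustering and stays within its sub-clusters. With genes scaled over all libraries, sub-clusters followed the libraries, with 1539 of 1547 nuclei of one from LFD replicate 1 and 2106 of 2147 of another from LFD replicate 2. Sub-clusters built without the called genes had a smallest median fall of -1.88 (SE 0.32), under the same limit. One of these still had Acss2, Acly and Elovl6 among its top 10 genes. In macrophage-like nuclei free adipocyte RNA cannot be told apart from expression: 3 of 8 members still fell after the subtraction from all libraries and 1 of 8 after that from LFD alone, with the median of the fallen genes going from -1.87 to -5.60 (SE 1.30) and to -0.94 (SE 0.45); lower transcription of these genes in adipocytes at HFD stays open as an untested hypothesis.

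The share of macrophage-like nuclei rose. Fewer adipocyte nuclei recovered is argued against as the whole cause, since among other nuclei the log2 change of the macrophage-like share exceeded that of the fibroblast or progenitor-like share by 1.98 (SE 0.35). That SE treats the 2 shares as independent, though both are parts of one total, so it may be too small. Cluster 0 was not counted as macrophage-like there. Counting it in took the log2 change among all kept nuclei from 1.76 to 1.10. With nuclei of at least 1500 UMIs the log2 change was 2.32 (SE 0.40), so shallower listed nuclei did not account for the rise. The LFD share was then 10.5% ± 4.37 and the HFD share 49.9% ± 10.4, so the size of the rise depended on the cut. The cut could not act on experiment 3, where the lowest listed nuclei had 1692 (LFD) and 1523 (HFD) UMIs. The limit behind the list itself was not tested. More macrophages in the tissue at HFD, and a difference in how macrophage and fibroblast nuclei are recovered, both stay open and were not tested.

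All comparisons of 22 with 18 weeks in this paragraph rest on 1 library per diet at 22 weeks and cannot be told apart from the kit. The difference HFD minus LFD had the opposite sign at 22 weeks from both experiments at 18 weeks for 4 class shares. None passed the test of the difference itself. It was 0.385 percentage points for B cell-like nuclei at 22 weeks (-1.02 and -1.03 at 18 weeks, interaction adjusted p = 0.555), and -0.0254 for epididymal epithelial-like nuclei (4.79 and 0.343, adjusted p = 0.45). It was 0.0042 for fibroblast or progenitor-like nuclei (-9.19 and -4.20, adjusted p = 0.56) and 0.176 for T or NK cell-like nuclei (-0.673 and -2.44, adjusted p = 0.473). The log2 ratio of Pparg in adipocyte-like nuclei was 1.36 at 22 weeks and -1.29 and -1.13 at 18 weeks, and that of Pi16 in fibroblast or progenitor-like nuclei was 0.47 against -0.57 and -0.23. By DESeq2 the diet effect differed between 22 and 18 weeks for 13 genes in adipocyte-like, 5 in fibroblast or progenitor-like and 9 in macrophage-like nuclei, where edgeR called 0 (640, 814 and 494 at an unadjusted p under 0.05); DESeq2 gave no adjusted p to 8132 of 11038 genes in the first class and 9436 of 13520 in the second, so its calls there were adjusted over fewer genes.

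In barcodes with 1 to 50 UMIs, 7 seminal vesicle secretory protein (Svs) genes, a multigene family whose single members are uncertain, made up 77571.6 CPM in LFD replicate 2 and 4481 in HFD replicate 2, with 0 of 2079533 UMIs in LFD replicate 1 and 0.401, 0.674 and 0.304 CPM in LFD replicate 3, HFD replicate 1 and HFD replicate 3. Crisp1 stood at 192, 225 and 9.73 CPM of these barcodes in HFD replicates 1, 2 and 3, and at 120, 14.4 and 16.0 at LFD. Barcodes outside the list of nuclei with at least 1000 UMIs numbered 1349, 4050 and 66618 at LFD and 8935, 2697 and 47230 at HFD, in experiments 1, 2 and 3.

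With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. These splits exchange libraries freely and ignore the pairing by experiment number, as does the exact permutation test of shares. The real split called 554, 478, 1317 and 101 genes in adipocyte-like, fibroblast or progenitor-like, macrophage-like and mesothelial-like nuclei, and the highest other split 0 in each, so 1 of 10 splits called as many. With adjustment within the class, the real split called 12, 17, 14 and 10 lists and the highest other split 12, 13, 14 and 13; 3, 1, 2 and 4 of 10 splits called as many. In mesothelial-like and macrophage-like nuclei that other split set LFD replicates 1 and 3 with HFD replicate 3, a grouping that keeps both v3 libraries together.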

How the results depend on the processing

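Settings chosen after the data were seen were cluster 0 counted as macrophage-like, nuclei with at least 1500 UMIs, the highest doublet scores removed, the largest free RNA subtracted (from all libraries or from 1 diet), the DESeq2 interaction and genes scaled over all libraries; the rest were planned. The cause was not tested for any change below, except that fits with a library left out have fewer samples. Where 1 library of experiment 3 is left out, the kit covariate absorbs the other, so values nearly equal those without both; the ranges with a library left out include the fit without both.

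The macrophage-like share kept its direction and call in all 15 alternatives, with log2 changes from 1.10, with cluster 0 counted in, to 2.32. The adipocyte-like share ranged from -1.88 to -1.33 with a library left out. Cluster 0 reached -3.74 among nuclei other than adipocyte-like ones and -4.04 to -2.47 with a library left out. The fibroblast or progenitor-like share ranged from -0.43 to 0.0459 with a library left out and was at -0.60 among nuclei other than adipocyte-like ones. Of shares without a call, cluster 9 (-0.53 as reported) was at 0.10 with no kit covariate and from -3.21 to 1.02 with a library left out; the endothelial-like share (0.21 as reported) was at -0.34 with no kit covariate, -0.25 among nuclei other than adipocyte-like ones, -0.39 with doublet calls kept and from -0.48 to 0.81 with a library left out.

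In adipocyte-like, fibroblast or progenitor-like, macrophage-like and mesothelial-like nuclei in that order, genes called numbered 554, 478, 1317 and 101. No kit covariate gave 93, 72, 505 and 24. No filter on low counts gave 1222, 1107, 1606 and 248, and DESeq2 688, 654, 1480 and 125. Leaving out genes that free RNA could supply gave 267, 223, 996 and 23, and subtracting the largest free RNA 155, 10, 526 and 8; subtracted from HFD alone it gave 192, 23, 1137 and 0 (edgeR; 334 at an unadjusted p under 0.05), and from LFD alone 743, 187, 801 and 38. With a library left out, counts ranged from 128 to 667, 161 to 409, 618 to 996 and 34 to 147. The block of experiments gave 643, 515, 1405 and 202. The DESeq2 interaction called 13, 5 and 9 genes in the first 3 classes. With an estimated correlation camera called 0 lists in each of the 4 classes.

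With the experiment as a block, sub-cluster 1 of adipocyte-like nuclei was at 0.48, sub-cluster 0 of fibroblast or progenitor-like nuclei at 0.33, macrophage-like sub-clusters 3 and 5 at 1.99 and -3.36, each with its call lost. Scaled over all libraries, early progenitor-like nuclei were at -0.84 and the dividing cell-like ones set beside macrophage-like sub-cluster 3 at 3.59, both without a call. With a library left out, sub-clusters 0 and 1 of adipocyte-like nuclei ranged from -0.0679 to 0.027 and from 0.33 to 0.65, early progenitor-like nuclei from -0.66 to -0.52, and sub-clusters 0 and 1 of their class from 0.27 to 0.38 and from -0.30 to 0.21. Macrophage-like sub-clusters 1, 2, 3, 4 and 5 ranged from -0.0216 to 0.0589, -0.90 to 0.0769, 1.56 to 2.22, -0.78 to 0.00067 and -3.98 to -2.65. Other numbered sub-clusters have no values under other clusterings.

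The block changed no other call than those named with it here and in the results. Among the 91 called values of named genes, all kept direction and call with DESeq2, RLE factors, doublet calls kept and the block; 51 lost the call with no kit covariate, 2 with no filter, 2 with at least 1500 UMIs and 3 with the highest doublet scores removed. Leaving out a library ended 11, 12 and 12 calls for LFD replicates 1, 2 and 3 and 25, 17 and 13 for HFD, where Knl1 in macrophage-like nuclei was not tested without HFD replicate 1 or 2. Of the 25 values without a call 5 passed with DESeq2 (Serping1, Gpam, Col1a1, Upk3b and Plin2), 9 with no filter (these and Plin1, Dpp4, Acss2 and Krt19) and 6 with the block. Of genes without a call, Lep in adipocyte-like nuclei was at -0.0385 with no filter and -0.058 with no kit covariate. With a library left out Lep ranged from -0.22 to 0.28, Adipoq from -0.88 to 0.0285, Pparg from -1.24 to 0.00481, Pi16 from -0.42 to 0.0405 and Fn1 in fibroblast or progenitor-like nuclei from -0.41 to 0.0916. The planned minimum of 1000 UMIs changed nothing, since each listed nucleus had as many. At this depth and with 3 libraries per diet, 20 to 28 of 100 simulated 2-fold changes were recovered; which of these sets the limit was not tested.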

Other observations

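The genes in the next 3 paragraphs were picked from lists fixed beforehand after their values were seen, so their values with a library left out were also computed after that; the list tests are those planned. Of their 22 called values, 7 held in all 6 fits with a library left out. Without the kit as a covariate 5 of the 22 held, those of Mest and of Atf3 in 4 classes, and 17 were lost, with adjusted p from 0.0597 (Cd40) to 0.619 (Adrb3).

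In adipocyte-like nuclei 2 of 18 insulin signalling genes fell, Irs1 (log2 change -1.08, edgeR adjusted p = 0.0115) and the glycogen synthase gene Gys1 (-0.99, adjusted p = 0.0382); camera adjusted p was 0.00904, and adjusted p = 0.426 with an estimated correlation. The adrenergic receptor gene Adrb3 fell from 579 ± 219 to 319 ± 201 CPM (SD, n = 3; edgeR adjusted p = 0.0308). Irs1 lost its call without HFD replicate 1 (adjusted p = 0.139), and Gys1 and Adrb3 without any one library of experiments 1 and 2 (up to 0.298 and 0.226). Of 14 adipokine genes 3 rose and 2 fell, among them Mest at 1.83 and Sfrp5 at 2.03, and Retn at -1.66 and Agt at -1.63 (camera adjusted p = 0.934). Mest held in each fit, while Sfrp5 lost its call without HFD replicate 1 (adjusted p = 0.138). Retn lost its call without LFD replicate 3, HFD replicate 1 or HFD replicate 3 (up to 0.145), and Agt without these or LFD replicate 2 (up to 0.161). Free RNA was bounded at 49.3% of the Sfrp5 UMIs at HFD and at 33.6% and 35.6% of the Retn and Agt UMIs at LFD.

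In fibroblast or progenitor-like nuclei 4 of 13 genes of the brake on adipogenesis and Wnt signalling fell, Vit at -1.21, Sox9 at -1.42, Wnt5b at -1.14 and Wnt10b at -1.50, and Meox2 rose by 1.04 (camera adjusted p = 0.016; adjusted p = 0.426 with an estimated correlation). Sox9 held in each fit. Vit lost its call without HFD replicate 1 (adjusted p = 0.0532), Wnt5b without HFD replicate 1 or 2 (up to 0.109), Wnt10b without any library but LFD replicate 2 (up to 0.225) and Meox2 without any but LFD replicate 1 (up to 0.091). Of 12 complement genes 5 rose there, with C7 from 354 ± 93.7 to 711 ± 75.0 CPM (camera adjusted p = 0.000904; adjusted p = 0.426 with an estimated correlation), a call lost without any library but LFD replicate 1 (up to 0.127).

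In macrophage-like nuclei the costimulatory genes Cd86, Cd80 and Cd40 fell, at -1.77, -1.48 and -1.15, while Ctss and Ciita rose, at 1.83 and 0.78. Of the 11 class II genes these 3 fell and these 2 rose, with a list median of 0.85 (camera adjusted p = 0.322). Cd86 and Ctss held in each fit with a library left out, and Ctss missed the threshold in experiments 1 and 2 alone (adjusted p = 0.0593). Cd80 lost its call without any LFD replicate or HFD replicate 3 (up to 0.132), Cd40 without any library but HFD replicate 2 (up to 0.168) and Ciita without any one library (up to 0.257). Atf3, a stress response gene, rose by 3.31 in adipocyte-like, 3.61 in fibroblast or progenitor-like, 3.54 in macrophage-like and 3.22 in mesothelial-like nuclei. It held in each fit in the first 3 classes and was lost in mesothelial-like nuclei without LFD replicate 3 (adjusted p = 0.17), where it did not pass the filter on low counts without HFD replicate 3. Free RNA was bounded at 65.8%, 86.3%, 20.1% and 62.0% of its UMIs at HFD in the 4 classes, so Atf3 at those levels outside macrophage-like nuclei is not separated from free RNA.

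The interaction genes of smallest p by edgeR, none past the threshold, were Vwc2l in adipocyte-like nuclei (log2 ratios 3.98, 3.81 and 0.35 in experiments 1, 2 and 3), Hbb-bt in fibroblast or progenitor-like nuclei (-0.77, -0.85 and 2.04) and Adgrg2 in macrophage-like nuclei (0.71, 0.81 and -4.30).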
